A study of Rattus norvegicus with 3 samples.

How the data were processed

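ChIP-seq with an antibody to Seh1 was performed on rat OPC and on iOL after 1 day of T3, with 1 library each, and with IgG on iOL; the IgG library has no values in the comparisons. Per the labels' protocols, cells were fixed with 1% formaldehyde for 10 min, quenched with 125 mM glycine, sonicated and immunoprecipitated, and libraries were made with a KAPA HyperPrep kit. Bowtie2 and HOMER are named in the submitters' processing notes, without versions, with builds rn6 and hg18 and no role for either. Trimming, duplicate removal, peak thresholds and the treatment of reads with several equal matches are not given in the sources used here. The last of these could move peaks among repeated sequences such as 7SL and 7SK copies.

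The authors deposited a peak list of positions per Seh1 library, without scores, and 1 annotated table. That table is recorded under the iOL library, but per the file headers it was written by HOMER's annotatePeaks.pl on rn6 from a peak file named for Seh1 in OPC and IgG in iOL. All 9084 of its intervals equal intervals of the OPC list and 0 equal intervals of the iOL list. It was therefore used as the annotation of the OPC peaks, and per its header name the OPC peaks appear to have been called against the IgG of iOL. The remaining 33 OPC peaks, all on scaffolds, have no annotation. The caller's score per peak in the deposited table has no definition in the header. All scores lie on multiples of 0.638, so neighbouring scores can differ by 1 step of the caller's count. The same table gives a focus ratio, a fraction from 0 to 1 that the authors' caller reports per peak, with a median of 0.778. It was not used in any test. The OPC list runs in order of falling score. The order of the iOL list is not stated, so its use as a rank is an assumption. Excel-style dates replaced 19 gene symbols, and genes were matched by their numeric ID instead. Of the table's intervals 99.2% had an ID in the gene name table of assembly GRCr8, which served for names and gene order only.

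Peaks were called shared when they overlapped by at least 1 bp. The count was set against 10000 random relocations within the chromosome, whose length was taken as the largest peak end. Class shares have exact binomial 95% intervals and were compared by Fisher's exact test. Scores were compared by permutation tests with 100000 resamples, two-sided, and p-values were adjusted by Benjamini-Hochberg within each family of tests: 12 classes of shared peaks, 11 distance bins, 22 chromosomes, 15 gene lists, and 5 contrasts each for medians, for means and for means without the highest peak. Promoter means 1000 bp upstream to 100 bp downstream of a TSS in HOMER's usual setting; distances of the promoter class ran from -998 to 617 bp, because a class can refer to another transcript than the nearest TSS. The tests by score step, distance bin, chromosome, 7SL and 7SK copy, RatSatRep2 copy and CpG island were chosen after the files had been seen. Peaks within 300 bp of the TSS of Rn7sl1 were counted as 7SL copies.

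A gene had a peak when it was the table's nearest gene. Each list was set against 10000 random lists in which every gene was replaced by 1 of its 5 nearest coding neighbours on either side in gene order, among 18533 genes, of which 30.1% had an OPC peak. The percentile of a list is its place among these draws. A list passed when the two-sided share of draws as extreme, adjusted by Benjamini-Hochberg over the 15 lists, was under 0.05, which describes this peak list and not OPC at large, since genes are not replicates. This matching replaced the planned matching on the length of surrounding genome, which needs an rn6 annotation, and it was chosen after the files had been seen. Of 459 list entries 450 were in the background. On simulated data the list test found 96% of 100 lists of 30 genes with planted peaks and called 2% of 300 without. Lists were drawn at random, peaks were shuffled over all genes, and each planted gene then gained a peak with a chance of 60%. The 2% therefore does not cover effects of surrounding genome or of gene clusters, and the 96% does not cover weaker excesses. The overlap test recovered 50.0 of 50 planted shared peaks, and in 1 of 10 runs with none planted under 5% of relocations reached the count. Apart from planted peaks, the simulated iOL peaks were placed at random within chromosomes, as in the relocation itself. These runs therefore check the counting and do not cover peaks that cluster along chromosomes.

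Gene ties for iOL peaks used the fact that the positions nearest to 1 TSS form an interval. In 10 folds of held-out OPC peaks, 1652 of 1666 peaks placed in this way (99.2%) went to their own gene. TSS positions for these ties were inferred from the distances of OPC peaks, and iOL distances were checked only to a tolerance of 600 bp on held-out OPC peaks. Named items followed a rule fixed before the data were examined: the 10 highest-scoring OPC peaks, the 10 shared peaks with the widest overlap (12 are given, because 4 were tied), up to 6 genes per list nearest to a TSS, and 16 fixed genes; some genes that this rule names are not reported here. The iOL list has no score and 1 width, so the rule gave no top iOL peaks beyond order by position, and none are named by it. For iOL, the genes named were chosen after their values were seen.

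Planned steps that needed an rn6 sequence or annotation were not run: motif tests, soft-masked repeats, location classes and gene lists of iOL with the test of stages, and relocation by distance to a TSS. Alternatives covered the overlap rule, stricter peak sets, the promoter definition and the gene assignment. Others were added after the data had been seen: relocation within 500 kb, circular shifts, the removal of 7SL, 7SK and RatSatRep2 copies, low-scoring peaks alone, peaks outside annotated repeats, and mean scores without the highest peak of a class. Calculations used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and Matplotlib 3.10.9.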

Results

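Chromatin bound by Seh1, a protein of the nuclear pore complex, was profiled by chromatin immunoprecipitation and sequencing (ChIP-seq) in rat oligodendrocyte progenitor cells (OPC) and in immature oligodendrocytes (iOL) after 1 day of triiodothyronine (T3) at 60 nM, which drives OPC to differentiate. The cells came from the forebrain of Sprague Dawley pups at postnatal day 1 to 2. One Seh1 library was made per stage, together with 1 IgG library of iOL whose profile was not analysed here. The OPC list held 9117 peaks of 205 bp and the iOL list 6704 peaks of 209 bp, on rat build rn6. Read totals were not given in the sources used here, so the depth of each library is unknown and intervals on shares cover counting error only. With 1 library per stage there was no replicate error, and each test below compares the peak lists, not the stages.

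The first comparison asked which Seh1 peaks of OPC were also called in iOL. Peaks at copies of 2 abundant small nuclear and cytoplasmic RNAs were called in both lists: 20 of 20 peaks at copies of 7SL, the RNA of the signal recognition particle, and 20 of 21 at copies of 7SK, the RNA that holds the elongation factor P-TEFb inactive. Both lists also had a peak at the promoter of Rmrp, the RNA of the RNase MRP enzyme (chromosome 15, 27739078 to 27739282), in the last exon of the ubiquitin gene Ubb (chromosome 10, 48881442 to 48881646), and in exons of the thymosin gene Tmsb4x and of the lipid carrier gene Apoe. Outside 7SL and 7SK copies, 118 of 9076 OPC peaks were shared, 1.30% (95% exact binomial interval 1.08 to 1.55%). The exon peaks of Ubb, Tmsb4x and Apoe and the Rmrp promoter were picked after their values were seen.

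In all, 158 OPC peaks overlapped an iOL peak by at least 1 bp, which was 1.73% of the OPC list (95% exact binomial interval 1.48 to 2.02%) and 2.36% of the iOL list (2.01 to 2.75%). Relocating the peaks at random within their chromosomes gave 9.81 ± 3.12 shared peaks (SD over 10000 relocations) and at most 29, so that the observed count was 16.1-fold higher and no relocation reached it. Overlapping peaks shared a median of 168 bp. The 12 widest overlaps, 204 or 205 bp, were at 6 copies of 7SL and 7SK near Rpl35a, Six6, Cdc5l, Olr551 and RGD1562618, a RatSatRep2 repeat near Bche, a LINE repeat near RGD1306186, a CpG island near the histone gene Hist1h2bo, the 3' end of Spint1, a simple repeat near Kin and an intergenic site near Dse. Shared peaks lay between genes more often than other OPC peaks, 70.1% of 157 annotated shared peaks against 56.5% of 8927 others (Fisher's exact test, two-sided, adjusted p = 0.00148), and in introns less often, 17.8% against 29.6% (adjusted p = 0.00204). No peak in a SINE repeat was shared, 0 of 509 (Fisher's exact test, adjusted p = 0.000503). Promoter peaks made up 3.18% of shared and 4.03% of other peaks (Fisher's exact test, adjusted p = 0.836).

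The second comparison set the strength of the OPC peaks, by the caller's score in the authors' deposited table, against where they lay. The strongest OPC peaks stood at 7SL and 7SK copies: these were 29 of the 40 highest-scoring peaks, and 31 of the 40 were shared with iOL. The peak at Rn7sl1, a 7SL gene (chromosome 6, 91456961 to 91457165), had a score of 116.8 and a peak at another Rn7sl1 copy (91680286 to 91680490) a score of 106.6. Other 7SL copies followed near Wbscr27 (score 96.4), near Ube2g1 (67.7), in an intron at Neto2 (64.5), near RGD1562618 (54.9) and near Gja6 (51.7), with a 7SK copy near Gsta4 at 62.6. The median score was 43.1 over 20 copies of 7SL and 17.2 over 21 copies of 7SK, against 7.66 over all annotated OPC peaks.

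Outside these RNAs the highest scores belonged to a region of chromosome 4 called in OPC alone. The top peak of the list (77447846 to 77448050, score 197.3) lay between genes, 41.6 kb downstream of the transcription start site (TSS) of Pdia4, a protein folding enzyme of the endoplasmic reticulum. A CpG island peak 46.4 kb away (77401233 to 77401437, score 100.2) lay at -54.3 kb from the TSS of Ezh2, the methyltransferase of Polycomb complex PRC2. Neither of these peaks overlapped an iOL peak. Their focus ratios, 0.639 and 0.702, were below the median of 0.778, which was not tested. The only IgG library is of iOL, so background of OPC in this region was not measured. The region is therefore not shown to be bound by Seh1 in OPC alone. Peaks in copies of RatSatRep2 had a median score of 8.94 over 279 peaks against 7.66 over 8805 others (permutation test with 100000 resamples, two-sided, adjusted p = 2.5e-05), and 17 of the 279 were shared.

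**Figure D1:**
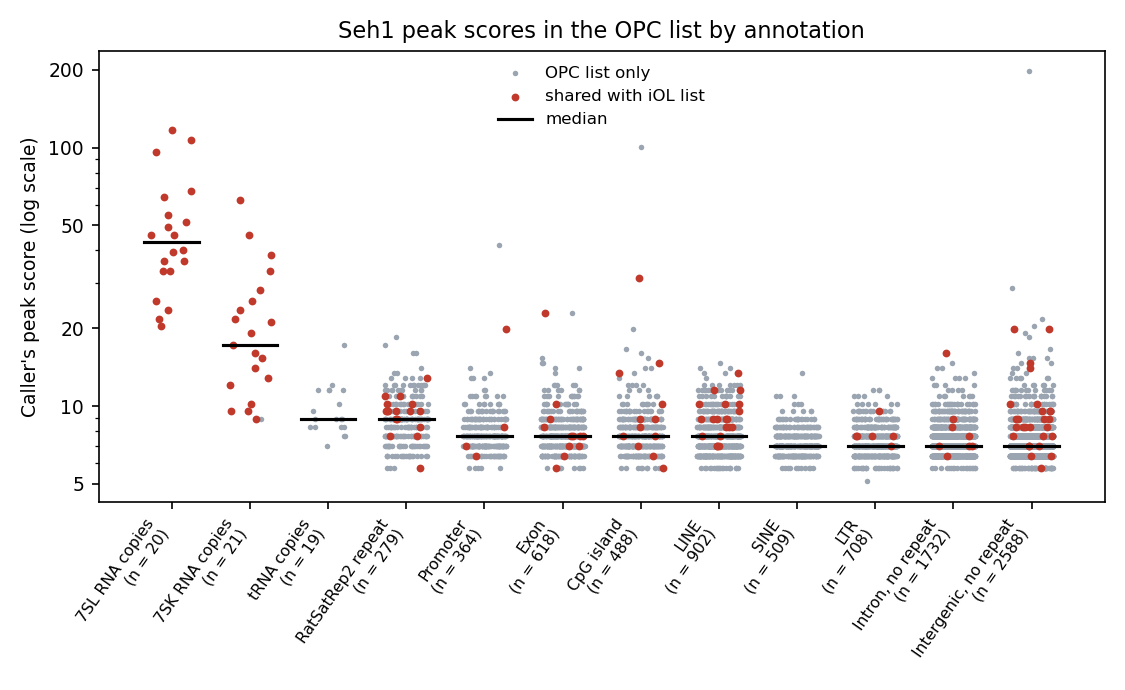
Score of each OPC peak (vertical axis, log scale, the caller's score) by annotation of its centre (horizontal axis, with the number of peaks); red points are peaks that overlap an iOL peak, grey points those that do not, and bars are medians. The 7SL and 7SK copies, with medians of 43.1 and 17.2, stand above the other classes shown, whose medians lie between 7.02 and 8.94. CpG island, LINE, SINE and LTR labels are given only to peaks between genes or in introns.

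Scores covered 5.11 to 197.3 with quartiles of 7.02 and 8.3. They fell on whole multiples of 0.638, within 0.0051 below a score of 10 and 0.051 above it, so that the median peak held 12 steps and 91.0% of peaks held 9 to 14. Shared peaks had a median score of 9.58 over 157 peaks and the others 7.66 over 8927 (permutation test, two-sided, adjusted p = 2.5e-05). Without 7SL and 7SK copies the medians were 8.3 and 7.66 (permutation test, adjusted p = 0.598), while the means, 9.38 and 7.68, differed (adjusted p = 0.00532). Promoter peaks and other peaks had the same median of 7.66, and so had CpG island peaks and the rest. The CpG island label was given only between genes or in introns, so islands at promoters and exons fall in the rest. Means were higher in both classes, 8.29 against 7.80 at promoters (permutation test, adjusted p = 0.0352) and 8.16 against 7.80 at CpG islands (adjusted p = 0.0447). The highest promoter peak was the 7SL copy at Rn7sl1 (score 116.8), and the highest CpG island peak was the one near Ezh2 (100.2). Without the highest peak of the class, which lowers the class mean by construction, the means were 7.99 and 7.97, and neither difference passed (permutation test, adjusted p = 0.273 for each).

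The share of OPC peaks found in iOL rose with the score. It was 0.710% of 1690 peaks with 8 to 10 steps, 5.03% of 477 peaks with 15 to 16 steps, 16.7% of 66 peaks with 21 to 30 steps and 82.4% of 17 peaks above 60 steps. Without 7SL and 7SK copies, 5 of 12 peaks with 31 to 60 steps were shared (41.7%, 95% exact binomial interval 15.2 to 72.3%), and 0 of the 3 peaks above 60 steps.

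**Figure D2:**
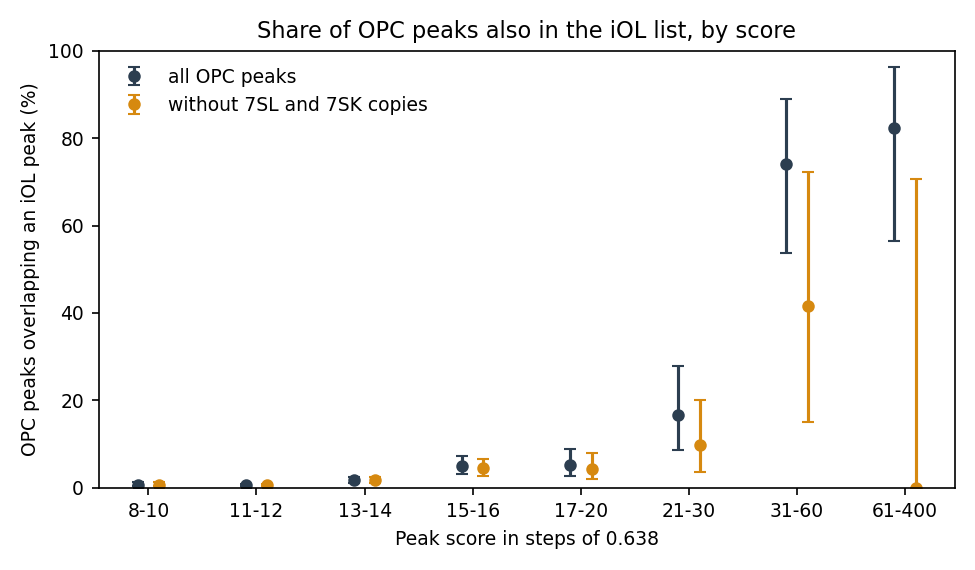
Percent of OPC peaks that overlap an iOL peak (vertical axis) by score in steps of 0.638 (horizontal axis), for all OPC peaks and without 7SL and 7SK copies; bars are 95% exact binomial intervals. The share rises from 0.710% at 8 to 10 steps to 82.4% above 60 steps when all peaks are taken.

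The third question was where Seh1 peaks of OPC lie relative to genes; the authors' annotation at hand covers 9084 OPC peaks and no iOL peak. Peaks lay mostly between genes (56.7%, 95% exact binomial interval 55.7 to 57.8%) and in introns (29.4%, 28.5 to 30.4%). Exons held 6.80% (6.29 to 7.34%), promoters 4.02% (365 peaks, 3.62 to 4.44%), transcription termination sites 1.40%, 3' UTRs 0.837% and 5' UTRs 0.705%. Finer labels, given only to peaks between genes or in introns, put 5.37% of all annotated peaks in CpG islands. They put 9.93% in LINE repeats, 7.79% in LTR repeats and 5.60% in SINE repeats. CpG islands and repeats at promoters, exons and UTRs are not counted in these shares. The share of the genome in each class was not measured, so these values show neither preference for a class nor avoidance of it. Among promoters with a peak were those of Thrb, the beta receptor for T3 (-87 bp), Id4, an inhibitor of oligodendrocyte differentiation (-82 bp), the signalling factor gene Bmp2 (4 bp), the proliferation marker gene Mki67 (75 bp) and the sterol regulator gene Srebf2 (48 bp).

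Peaks lay more often on the transcribed side of the TSS. Within 250 bp there were 288 peaks downstream and 121 upstream (exact binomial test, two-sided, adjusted p = 9.17e-16), and from 250 to 500 bp 193 and 67 (adjusted p = 1.38e-14). Farther out the excess was smaller but remained, with 1056 and 750 at 20 to 50 kb (exact binomial test, adjusted p = 2.31e-12) and 1333 and 1084 at 100 kb or more (adjusted p = 1.22e-06). It passed in 10 of 11 distance bins, all but 1 to 2 kb (108 and 103, exact binomial test, adjusted p = 0.783). The test took both sides as equally likely, but the length of genome on each side was not measured. Relocation by distance to a TSS was not run, so the excess is not shown to exceed that of random positions. Peak density downstream fell from 1152 peaks per kb of distance within 250 bp to 84.0 at 5 to 10 kb. The median distance to a TSS was 34.8 kb, 9.47% of peaks lay within 1 kb and 26.6% lay 100 kb or more away. The promoter share depended on its definition and reached 13.8% when any peak within 3000 bp of a TSS counted.

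**Figure D3:**
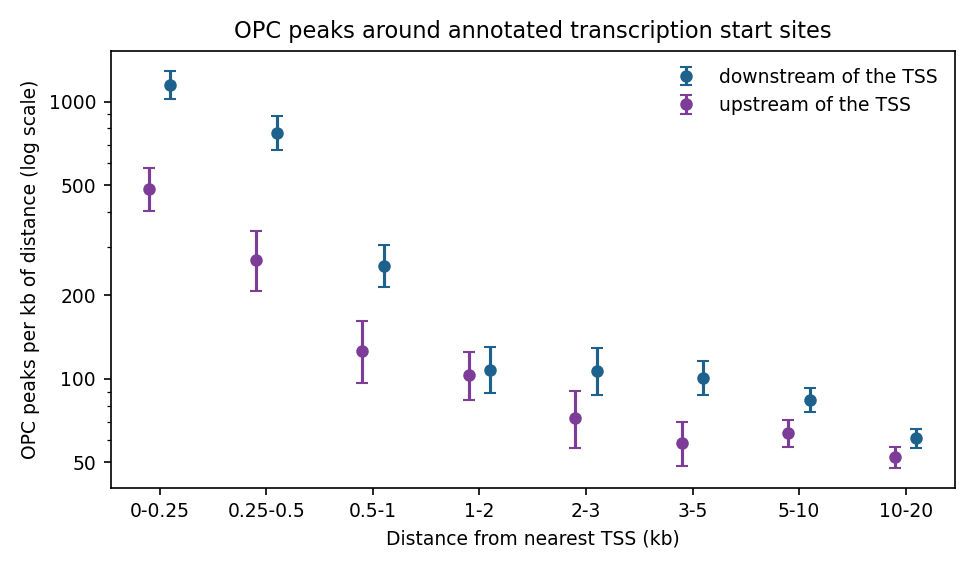
OPC peaks per kb of distance (vertical axis, log scale) in bins of distance from the nearest annotated TSS in kb (horizontal axis), upstream and downstream; bars are 95% exact Poisson intervals. Density downstream is 1152 peaks per kb within 250 bp, against 484 upstream, and both sides are near 100 at 1 to 2 kb.

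The fourth question was which genes the OPC peaks lay nearest to, asked for 15 gene lists fixed before the data were examined. Of 35 genes of Wnt, Notch and BMP signalling, pathways known to hold back oligodendrocyte differentiation, 24 had an OPC peak, against 14.2 ± 2.83 (SD) in random lists drawn from neighbouring genes (1.69-fold, percentile 99.95 of 10000 random lists). Their nearest peaks lay at the promoter of Bmp2, in the 5' UTR of the BMP antagonist gene Nog (149 bp), in introns of Fzd3 (480 bp) and Wnt7b (1297 bp), near Smad6 (-1447 bp) and in an exon of Chrd (4418 bp). The list mixes genes that act in these pathways with antagonists such as Nog, so its count gives no direction for differentiation. Of 22 astrocyte genes, 13 had a peak against 6.12 ± 1.95 (2.12-fold, percentile 99.85). In 4 of the 13 the nearest peak lay in an exon: Vim, the intermediate filament gene (453 bp, score 15.3), Apoe (1994 bp), the water channel gene Aqp4 (2857 bp) and the glutamine synthetase gene Glul (7764 bp). Fgfr3 and Acsbg1 had peaks at 1174 and -5905 bp. Long neuronal adhesion and synaptic genes, a control list, had a peak in 17 of 24 genes against 10.3 ± 2.27 (1.65-fold, percentile 99.73), with Opcml and Csmd1 among them within 2 kb of a TSS and Erbb4 and Magi2 further out.

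These 3 lists passed after adjustment over the 15 lists; the percentiles describe this peak list. Oligodendrocyte lists did not pass. OPC genes and differentiation inhibitors had a peak in 22 of 38 genes against 15.2 ± 2.84 (1.45-fold, percentile 98.68), with Id4, Lingo1 (122 bp), Etv5 (339 bp), Jag1 (452 bp), Matn4 (-1513 bp) and Sox9 (2674 bp) closest to a TSS. Myelin and mature oligodendrocyte genes had one in 17 of 34 against 12.2 ± 2.55 (percentile 95.17), with Nkx6-2, Opalin, Trim59, Nfasc, Hapln2 and Pllp nearest. Lineage regulators had one in 17 of 38 against 14.2 ± 2.79 (percentile 79.23), with Thrb, Nkx6-2, Nfasc, Erbb3 and Myrf among the nearest.

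Nucleoporin genes had a peak in 15 of 30 against 10.8 ± 2.46 (percentile 93.34), with Nup54, Nup98 and Ranbp2 within 1 kb of a TSS and Nup50, Nup62 and Nup88 next. Genes of the BAF and PBAF remodelling complexes, to which Brd7 belongs, had a peak in 12 of 27 (percentile 79.06), with Bcl7b, Smarcd2, Bcl11a, Dpf1, Dpf3 and Bcl11b nearest. Counts were 10 of 26 for cholesterol synthesis (Lss, Srebf2, Pmvk and Insig1 among them), 13 of 35 for the cell cycle (Mki67, Cdkn2a, Mycn, E2f3, Cdkn1c and Ccnd1) and 13 of 33 for cytoskeleton and process outgrowth (Gsn, Dock9, Map1b, Actb, Septin4 and Rac1), at percentiles 70.94, 47.32 and 59.15. Neuron genes had a peak in 9 of 28 (Nefl, Slc32a1, Tbr1, Rbfox3 and Snap25 among them; percentile 28.88). Microglia genes had one in 8 of 22 (Tyrobp, C1qb, Fcrl2, Csf1r, Cx3cr1 and Laptm5; percentile 69.0). Vascular and mural genes also had 8 of 22 (Col1a1, Cldn5, Acta2, Vwf, Cdh5 and Kcnj8; percentile 72.31). Ribosomal protein genes had a peak in 11 of 35 (Rpl3, Rpl15, Rpl11, Rpl7, Rpl23 and Rpl19; percentile 34.05). With peaks within 50 kb of a TSS, the astrocyte list alone passed (11 of 22 genes, 2.90-fold, percentile 99.98), while the Wnt, Notch and BMP list stood at percentile 98.43 and the long neuronal list at 59.75. No list passed without peaks in annotated repeats, a setting added after seeing the data, where the astrocyte list stood at 2.33-fold (percentile 99.59), the Wnt, Notch and BMP list at 1.73-fold (99.75) and the long neuronal list at 1.82-fold (98.55), folds no lower than with all peaks.

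**Figure D4:**
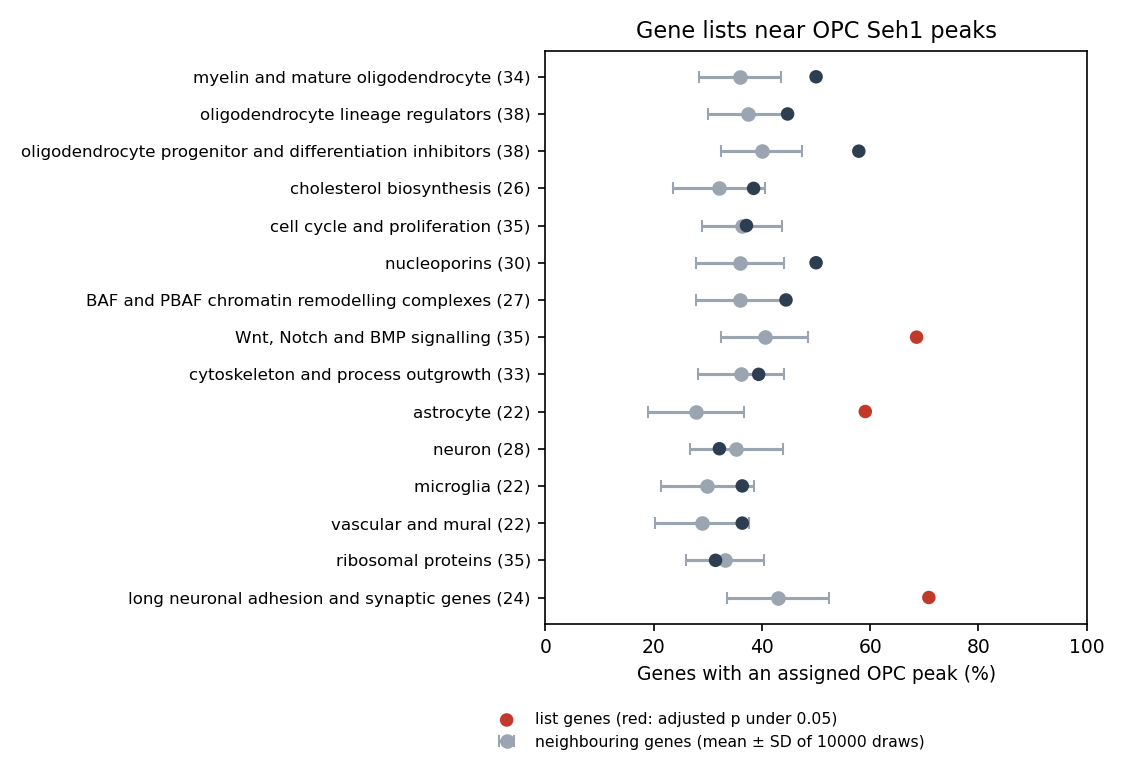
Percent of the genes of each list with an assigned OPC peak (horizontal axis; list sizes in parentheses on the vertical axis), beside the mean ± SD of 10000 random lists drawn from neighbouring genes; red points passed after adjustment. The Wnt, Notch and BMP list (24 of 35), the astrocyte list (13 of 22) and the long neuronal list (17 of 24) are red.

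Seh1 is named in the series title with Olig2, a transcription factor of the oligodendrocyte lineage, and Brd7, a bromodomain protein. In OPC no peak had Seh1l, Olig2, Olig1, Sox10, Mog, Cnp, Pdgfra, Cspg4, Zfp488 or Tcf7l2 as its nearest gene. Brd7 had 1 peak between genes at -42.0 kb (chromosome 19, 19630725 to 19630929, score 6.38). The myelin regulator gene Myrf had 2, in the last exon of a neighbouring transcript at -6.91 kb (chromosome 1, 226299285 to 226299489) and in an intron at 11.8 kb (226280608 to 226280812), each with score 7.66. The myelin gene Mbp had 3 peaks, the nearest in an intron at 29.2 kb (chromosome 18, 79435483 to 79435687, score 7.02). Mag, a myelin adhesion gene, had 1 intron peak at 14.1 kb (chromosome 1, 89346558 to 89346762, score 7.66), and Nkx2-2, a lineage regulator, had 4 intergenic peaks from 11960 to 410947 bp. These scores lie at or below the list's median of 7.66.

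For iOL, 1354 peaks (20.2%) could be tied to a gene because they lay between annotated OPC peaks or a TSS of the same gene, which limits them to genes with OPC peaks. Mbp had 3 such iOL peaks, at 22272, 27968 and 113809 bp from its TSS, and none overlapped an OPC peak. The myelin gene Mobp had 1 at 6.02 kb and the lineage regulator gene Sox8 1 at 10.5 kb. Thrb had 3, at 32.9, 70.6 and 242.0 kb. Another iOL peak lay 121 bp from the inferred TSS of the cell cycle gene E2f3, a distance below the tolerance of 600 bp. Others lay 1.53 kb from the TSS of Aqp4, 1.79 kb from that of the Notch target gene Hey2, 8.96 kb from that of the Wnt feedback gene Axin2 and 8.70 kb from that of the sulfatase gene Sulf2. Of the Wnt, Notch and BMP list 11 genes had a tied iOL peak, of the OPC and inhibitor list 6, of the myelin list 4 and of the astrocyte list 2. No test was made on these counts, since genes without OPC peaks could not be counted.

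Chromosome X was the exception in how the lists spread over chromosomes. It held 127 OPC peaks (1.39%) and 143 iOL peaks (2.13%), an odds ratio of 0.648 (Fisher's exact test, two-sided, adjusted p = 0.0106), and none of the other chromosomes among the 22 passed after adjustment. Chromosome 12 had the densest peaks in both lists, 7.04 per Mb in OPC and 4.40 in iOL.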

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

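Tests on repeats, 7SL and 7SK copies, RNA polymerase III genes, score steps and peak positions were chosen after the results had been seen. For the gene lists, the limit of 50 kb and the gene-body rule were planned, while the matching on neighbouring genes and the use of these values to weigh explanations were chosen after.

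Signals outside the main measurements were few. Unplaced or random scaffolds held 38 OPC peaks, of which 33 had no annotation, and 29 iOL peaks. The mitochondrial genome held 1 iOL peak and 0 OPC peaks. A repeated class column in the deposited table equals the first class column in 41.0% of lines, against 41.3% for columns matched by chance, and it is blank in 33 lines; it was not used.

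7SL and 7SK copies hold 29 of the 40 strongest OPC peaks and 40 of the 41 are shared. Pile-up on high-copy repeats whatever their kind is argued against, since 0.330% of 2119 LINE, SINE and LTR peaks exceed 20 score steps against 0.825% of 6062 peaks outside repeats (Fisher's exact test, p = 0.0216); satellite and RatSatRep2 peaks do so more often, 3.97% of 302 (p = 2.67e-05), so pile-up that depends on the kind of repeat is not excluded. Reads of 1 source gene placed on near-identical copies stay open; the variance of the steps over their mean is 23.7 across 7SL copies, which rules out equal placement but not copies of unequal identity. Enrichment at RNA polymerase III genes as a class may hold in part, since tRNA copies have a median score of 8.94 (permutation test, p = 0.00099) and 4.5S copies the same, while BC1 copies have 7.02 and 0 of these 58 peaks are shared. Among small RNA peaks left out of this test, the Rmrp promoter peak (score 19.8) was shared, as were 1 of 5 rRNA peaks and 0 of 2 snRNA peaks. The iOL IgG profile, not analysed here, would bear on each of these explanations.

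Few peaks are shared between the stages, 1.73% of OPC peaks. Peaks near the detection floor are a candidate explanation: outside 7SL and 7SK copies, 5.40% of 778 peaks with 15 steps or more were shared, against 0.700% of 6575 with 12 or fewer (Fisher's exact test, p = 7.94e-19). Calls shifted in position are argued against, since 0.960% of 8959 unshared OPC peaks have an iOL peak centre within 1 kb. A difference between the stages is untested and cannot be told apart from a difference between libraries with 1 library each, so the 2.36% of iOL peaks that are shared sets no bound on it.

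Of the 3 gene lists with more peaks than neighbouring genes, the astrocyte list kept its excess when peaks had to lie within 50 kb of a TSS, 2.90-fold, which argues against the size of the surrounding genome as its whole cause. The long neuronal list fell to 1.20-fold there, as an effect of surrounding genome would give, although it was 4.52-fold with peaks in gene bodies, where long genes hold more sequence by construction. The Wnt, Notch and BMP list stood at 1.67-fold, percentile 98.43, without passing, which leaves it open. High transcription in general could also place peaks in exons such as those of Vim, Apoe and Glul; ribosomal protein genes had 0.948 times the count of their neighbours and 0.406 times with peaks in gene bodies (percentile 0.82), which points against it, but they are short and neither ratio passed, so this stays open.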

How the results depend on the processing

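Settings listed in processing and marked as added were chosen after seeing the data. The count of 158 shared peaks was 129 with 50% of both peaks overlapping and 199 with centres within 500 bp. It was 343 with peaks extended by 1000 bp, 105 in the stricter part of each list, 63 among the first 1000 peaks of each, 101 without 7SL, 7SK and RatSatRep2 copies and 76 for OPC peaks of at most 14 steps; the smaller sets hold fewer peaks by construction, and the iOL order is assumed to be by score. It stayed above relocation in each of these, from 3.30-fold to 404-fold, and was 10.9-fold with relocation within 500 kb. Taking the annotated table as the iOL list gave 9084, because it holds OPC peaks. The promoter share of 4.02% became 13.8% within 3000 bp, 12.2%, 13.3% and 16.8% with the authors' wider classes, 4.71% in the stricter part of the list and 6.02% outside repeats. The rise outside repeats was fixed by the annotation, in which promoter peaks carry no repeat label. The same 365 promoter peaks were counted in both settings, among fewer peaks in all. Instead of 3 gene lists, 1 passed within 50 kb, 1 in the stricter part, 2 in gene bodies, 4 unmatched and 0 without repeat peaks; the cause was not tested. The Wnt, Notch and BMP list passed unmatched only (2.27-fold), and missed in gene bodies (1.53) and in the stricter part (1.70) too; the OPC and inhibitor list passed unmatched (1.93), the astrocyte list in all but the repeat setting, and the long neuronal list in gene bodies (4.52) and unmatched (2.34). Lists near a ratio of 1 changed side without passing: cholesterol synthesis 0.970 within 50 kb and 0.934 in gene bodies, ribosomal proteins 1.04 within 50 kb, 1.04 unmatched, 1.03 in the stricter part and 1.22 without repeats, neuron 1.85, 1.06, 1.17 and 1.42 in gene bodies, unmatched, stricter and without repeats, microglia 0.867 in gene bodies and cytoskeleton 0.969 without repeats. Over single lists and score contrasts, 60 of 85 comparisons kept direction and side of the threshold, 8 lost the call, 5 gained it and 12 changed side. No paired analysis was possible because each stage has 1 library.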

Other observations

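Tests named here were chosen after the values had been seen.

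Several genes collected many OPC peaks. Shox2, a homeobox gene, and Cdca7, a cell cycle gene, had 11 each, Veph1 had 10 and Agpat4 had 9. The T-box gene Tbx3 had 8, as did Mn1, and Bcl11a, a zinc finger gene of neurons and of the BAF complex, and Cyp26b1, which breaks down retinoic acid, had 7. These counts were not corrected for the length of genome around each gene and include distant peaks in repeats. Those of Veph1 included satellite peaks at -2729, -2732 and -2778 kb from its TSS, and those of Shox2 a 4.5S copy at 999 kb. Bcl11a also had 4 tied iOL peaks, from 103.0 to 764.7 kb from its TSS.

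Besides those of Ubb, Tmsb4x and Apoe, shared exon peaks included a peak in the haptoglobin gene Hp (chromosome 19, 42100159 to 42100363, score 7.66), and others in Twist2, Tmed2, the histone gene Hist2h2aa3, the olfactory receptor gene Olr1197, Rgl3 and Ankrd13d. A further exon peak had Crocc as its nearest gene but lay at -7914 bp from that TSS, so the exon may belong to another transcript. In all, 12 of 157 annotated shared peaks lay in exons, 7.64%, against 6.79% of the others (Fisher's exact test, adjusted p = 0.688), so exons were not more frequent among shared peaks by this test. An iOL peak also lay in the neighbourhood of the beta actin gene Actb at 2.02 kb from its TSS, and OPC had an Actb exon peak at 1.27 kb.

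OPC and iOL peaks lay near each other more often than after relocation. Within 10 kb, 912 OPC peaks had an iOL peak, the overlapping ones included, against 463 ± 21.7 (SD) after relocation within the chromosome and 680 ± 25.2 after relocation within 500 kb, a ratio of 1.34.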
